A study of Homo sapiens with 54 samples.

How the data were processed

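RNA of SW620 cells was measured on 54 Agilent dual-colour arrays, 3 in each of 18 groups: parental cells with DMSO or 5 compounds, and 6 knockout clones with DMSO or CCT251545. Cy3 carried the sample and Cy5 a common human reference RNA, per the labels' protocols. The intensity values (median signal and local background of each spot in each channel) came from 1 scan read by Agilent Feature Extraction, per the file headers. The files also hold processed signals, which that software had background-subtracted, detrended and dye-normalised, and their log10 ratio of Cy5 over Cy3, per the file headers. The deposited series matrix holds a log2 ratio per probe, and limma is named as its tool in the submitters' processing notes, which give no version. Compared with log2 ratios computed here, it was found to be the ratio of reference over sample (r = -1), so its sign was turned. Flags of the scanner software, 0 or 1 (other values such as outlier and well above background), were used as deposited.

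The analysis began from the intensity files. Median signals were background-corrected by normexp with an offset of 50 and normalised by loess within each array in limma 3.58.1 (R 4.3.3, data.table version 1.17.8). The written plan spoke of mean signals, but the files hold medians only. Control spots had no weight and spots with an outlier flag were left out, 92 to 252 per array. The value analysed was log2(Cy3/Cy5), with no normalisation between arrays. Of 58201 probes, 34982 had 1 gene symbol through the accessions that RefSeq lists for GRCh38.p14, which covered 25049 symbols; the array files name an older build, so no coordinates are given. The probe with the highest mean brightness stood for each symbol, and a symbol was tested when its probe was well above background in Cy3 on all 3 arrays of at least 1 group, which left 15392 genes.

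One linear model gave each of the 18 groups a mean, with 36 residual degrees of freedom, and limma's moderated test was read from contrasts of these means. The p-values are two-sided and Benjamini-Hochberg adjusted within each contrast, with a threshold of 0.05. Clone effects are means over both clones of a genotype, and the counts for untreated clones need both clones past the threshold in 1 direction. Gene lists, fixed before the data were examined, covered the Mediator kinase module, Wnt and beta-catenin targets, interferon targets, NF-kappaB targets, immediate-early genes, hypoxia and glycolysis, cholesterol and fatty acid synthesis, cell cycle and E2F targets, p53 targets, TGF-beta and BMP targets, Notch targets, intestinal differentiation, epithelial and mesenchymal markers, ATF4 and unfolded protein response, heat shock, AhR and NRF2 targets, MYC and ribosome biogenesis, and other cell types. These 18 lists were tested with camera in 18 comparisons at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Signature scores are means of signed log2 changes with 95% intervals from the pooled spread and exact two-sided permutation tests, over 400 arrangements for 2 clones, with 0.005 the smallest p possible. Differences between genotypes were tested otherwise, by permuting same-numbered pairs pooled over both clones. There were 84 splits against parental cells and 924 between knockout genotypes. Those p-values treat the pairs of both clones as independent and do not measure the spread between clones.

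The genes named in the text follow a rule fixed in advance. CDK8 and CDK19 are always given. Among called genes whose arrays did not overlap between the groups, the 10 highest and 10 lowest changes were taken for CCT251545 in parental cells and for the double KO, and 5 and 5 for each single knockout. For the other compounds and for treated clones, the values of the 20 genes of parental CCT251545 are given with the 3 highest and 3 lowest of their own, and for differences and interactions the 5 largest. From each list described, 2 to 4 members with the smallest adjusted p are given; uncharacterised loci are not named, and some genes that the rule selects are not reported here. Of the other probes of named genes that were well above background, 24 of 24 changed in the same direction. A probe counts once for each comparison that names its gene, and some changed far less, such as an ASNS probe at 0.01.

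The pairing of replicate numbers was checked by correlating the deviations of arrays from their group means. Of 33 pairs of compound and DMSO arrays with 1 number, 32 correlated above 0.1 (0.04 to 0.87 over all), so that the numbers pair the samples except in CDK19 KO clone 2, where 1 pair was below. Knockout and parental arrays were not paired, with 6 of 18 pairs above 0.1. The arrays lay on 7 slides: CCT251545 and its DMSO arrays shared a slide in every pair, CCT251921 and MSC2530818 in 2 of 3, and SEL120-34A and Senexin B in 1 of 3. Arrays of 1 slide correlated at 0.407 after the group means were removed. Fits with the replicate number or the slide as a block are therefore given beside the counts. Other alternatives were Feature Extraction's processed signals, no background subtraction, Cy3 alone, the deposited matrix, scaling between arrays, no filter on dim probes, means over probes, a fit to the compared arrays alone, a log2 threshold of 1, and leaving out each array.

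The steps were tested on simulated data with the measured spread of the 15392 genes and 200 of them changed. The simulated arrays varied independently, unlike the measured arrays of 1 slide. For CCT251545 in parental cells, 41% of the genes changed by 0.5 and 92% of those changed by 1 were called, with 9 false calls. For both CDK8 KO clones against parental cells the shares were 33 and 86%, and for CCT251921 against CCT251545 they were 55 and 97%. A signature set to 0.7 was recovered as 0.698.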

Results

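Gene expression was measured in SW620, an established human colorectal cancer line, on 54 dual-colour oligonucleotide arrays. Each array set 1 sample, labelled with Cy3, against a common human reference RNA labelled with Cy5. The arrays made 18 groups of 3. Parental cells formed 6 groups, given DMSO (the solvent control), CCT251545, CCT251921, MSC2530818, SEL120-34A or Senexin B. The other 12 groups were 6 clones given DMSO or CCT251545, of which 2 each were labelled as lacking CDK8, CDK19 or both (double KO). CDK8 and CDK19 are paralogous kinases of the Mediator complex, which links transcription factors to RNA polymerase II. CCT251545 was given at 350 nM for 6 hours, and no dose is stated for the other compounds. The stated purpose was to examine the selectivity of CCT251545 with chemical and genetic tools. Between 39.6 and 57.8% of the probes on an array were well above background in Cy3, and the number of arrays limits the precision. Replicates correlated at 0.920 to 0.988 across genes, and 15392 genes were tested. The epithelial genes EPCAM and VIL1 had median log2 ratios of sample to reference of 2.37 and 3.56, with CDH17, LGALS4 and CDX1 nearer 0 at 0.58, 0.44 and 0.37. The connective tissue genes SPARC, COL1A2 and VIM had -6.41, -4.63 and -2.43, and COL3A1, well above background in Cy3 on 0 of 54 arrays, had -0.11. All changes are log2 values of sample over reference, so that a positive value is higher expression (the sign is opposite to that of the deposited matrix); errors are standard errors unless SD is written, and every group has n = 3 arrays. The p-values measure the spread among these arrays, since nothing beyond the replicate labels says that replicates were separate cultures.

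The targeted genes came first, as a check of the clone labels. The tested CDK8 probe had a mean log2 ratio of 1.40 ± 0.21 (SD, n = 3) in parental DMSO cells and of 0.33 ± 0.49 (SD, n = 3) in CDK8 KO clone 1, a change of -1.06 ± 0.27 (adjusted p = 0.0035). CDK8 KO clone 2 stood at 1.32 ± 0.41 (SD, n = 3), a change of -0.07 ± 0.27 (adjusted p = 0.893). The double KO clones changed by -0.47 (adjusted p = 0.211) and -0.80 (adjusted p = 0.0273), and the CDK19 KO clones by -0.48 (adjusted p = 0.205) and -0.15 (adjusted p = 0.76). The CDK8 call in double KO clone 2 was lost without its DMSO replicate 3 (-0.67, adjusted p = 0.13) and without parental DMSO replicate 3 (-0.68, adjusted p = 0.102). The CDK19 probe was higher, not lower, in the clones labelled CDK19 KO, by 0.83 ± 0.18 (adjusted p = 0.00072) and 1.12 ± 0.18 (adjusted p = 1.51e-05) over the parental level of -1.67 ± 0.20 (SD, n = 3). It was also higher in the CDK8 KO clones (1.30, adjusted p = 7e-07, and 1.15, adjusted p = 6.42e-06) and in double KO clone 1 (0.60, adjusted p = 0.00961), and double KO clone 2 gave 0.23 (adjusted p = 0.395). The call in double KO clone 1 was lost without its DMSO replicate 2 (0.44, adjusted p = 0.108) and without parental DMSO replicate 1 (0.53, adjusted p = 0.0522). The CDK19 values go against the labels, and those of CDK8 bear out only some of them. A knockout by small deletions need not lower the transcript, and a probe outside the deleted part checks nothing, so the clones are called by their labels throughout. Of the other Mediator kinase module genes, MED13L was higher in CDK8 KO clone 1 (0.57, adjusted p = 0.0345) and in the clones labelled CDK19 KO (0.62, adjusted p = 0.0193, and 0.80, adjusted p = 0.0038), and CCNC was lower in double KO clone 1 (-0.36, adjusted p = 0.0444).

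**Figure D1:**
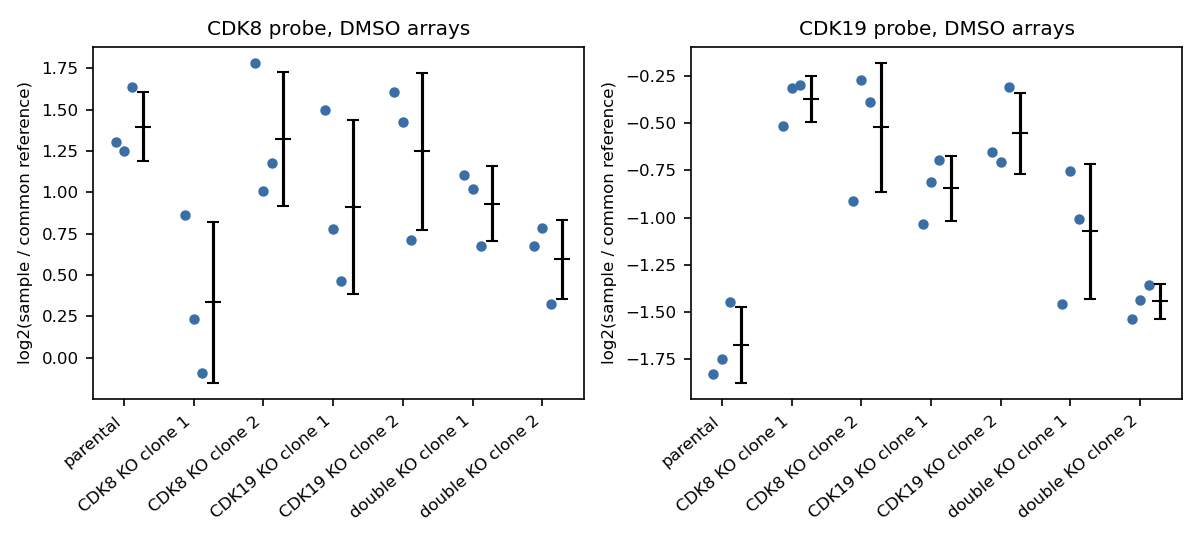
Log2 ratio of sample to common reference (vertical axis) of the CDK8 probe (left) and the CDK19 probe (right) in the DMSO arrays of parental cells and the 6 clones (horizontal axis); points are arrays, bars the mean ± SD of 3. CDK8 was lowest in CDK8 KO clone 1 (0.33), and CDK19 was lowest in parental cells (-1.67).

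The first comparison asked which genes CCT251545 changed in parental cells. RASD1, a small Ras-related G protein gene, rose most, by 2.16 ± 0.24 (adjusted p = 5.47e-07). RDH10, which oxidises retinol, rose by 1.26 ± 0.16 (adjusted p = 3.89e-06), and DKK1, a secreted Wnt antagonist, by 1.07 ± 0.14 (adjusted p = 1.23e-05). The sugar transporter family gene SLC35D3 (1.53), the keratin KRT23 (1.33), the peptide hormone gene EDN1 (1.23), the Wnt ligand WNT11 (1.13), the growth factor binding protein FGFBP1 (1.00), the arginine deiminase PADI1 (0.95) and the surface glycoprotein CD24 (0.92) rose as well, with adjusted p from 0.000106 to 0.0239. TNFRSF12A, the receptor of the cytokine TWEAK, fell by 0.85 ± 0.11 (adjusted p = 8.2e-06). CDKN2C (-0.74, adjusted p = 0.000125) and CDKN2D (-0.64, adjusted p = 0.0088), inhibitors of cyclin D kinases, fell, as did the transcription factor KLF2 (-0.85), the cell cycle regulator SERTAD1 (-0.82), HCFC2 (-0.74), the cilium gene TMEM107 (-0.61), the clock gene BMAL1 (-0.58), the non-coding GASAL1 (-0.52) and KIAA0513 (-0.50). Other probes gave less: 0.74 for KRT23, 0.65 for EDN1, -0.44 and -0.46 for HCFC2, and -0.45 and -0.24 for GASAL1. In all, limma called 53 genes, 41 higher and 12 lower. The replicate numbers pair these arrays and each pair lay on 1 slide; the count was 149 with the replicate number as a block and 312 with the slide as a block, but 6 with scaling between arrays and 1 in a fit to the compared arrays alone. Leaving out CCT251545 replicate 3 gave 31 genes and leaving out DMSO replicate 2 gave 35. When each of the 6 arrays was left out in turn, CDKN2D and EDN1 kept their calls in 4 fits, BMAL1, GASAL1 and KLF2 in 3, FGFBP1, PADI1 and TMEM107 in 2 and KIAA0513 in 1.

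By the gene lists chosen before the data were examined, Wnt and beta-catenin targets were higher with CCT251545. Of 22 measured genes, 3 rose and none fell among all genes tested (DKK1, the ion transporter SLC12A2 at 0.78 and the Wnt receptor ligase RNF43 at 0.60), and 9 were higher and 1 lower when adjusted over the list alone. The list's median change was 0.31 (camera adjusted p = 5.41e-18; adjusted p = 4.16e-06 with an estimated correlation), and the mean of its members lay between 0.34 and 0.38 on each of the 3 slides. Of 21 genes of cholesterol and fatty acid synthesis, SQLE, the squalene epoxidase, rose (0.65, adjusted p = 0.0227), and 3 were higher when adjusted over the list alone. The median of that list was 0.19 (camera adjusted p = 1.69e-11; adjusted p = 0.0313 with an estimated correlation). Intestinal differentiation markers (camera adjusted p = 0.00263) and MYC and ribosome biogenesis genes (0.0329) ranked higher than other genes, without 1 member called. With an estimated correlation these had adjusted p = 0.274 and adjusted p = 0.478, and with the slide as a block as well the intestinal list had adjusted p = 0.0149. Interferon targets (camera adjusted p = 0.0132; adjusted p = 0.416 with an estimated correlation) and heat shock genes (camera adjusted p = 0.0132; adjusted p = 0.438 with an estimated correlation) ranked lower, also without a member called.

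The other compounds were compared with DMSO to ask whether they changed the same genes. With CCT251921 all 20 of the genes named above were called in the same direction, RASD1 at 2.31 ± 0.24 and CDKN2C at -0.80 ± 0.11, though EDN1 (0.97 to 1.08) and CDKN2D (-0.52 to -0.485) lost their calls without any 1 of the 6 arrays. INSIG1, which restrains cholesterol synthesis and is itself a sterol-regulated gene, rose most, by 2.48 ± 0.23 (adjusted p = 2.27e-09), and SMIM5, a small membrane protein gene, fell by 1.19 ± 0.28 (adjusted p = 0.0184; -0.25 by another probe). Of the 21 cholesterol and fatty acid synthesis genes, 12 rose and none fell (17 higher when adjusted over the list alone), with a median of 0.65 (camera adjusted p = 5.24e-45; adjusted p = 4.17e-06 with an estimated correlation). These held INSIG1 and SQLE (1.31). The list's mean was 0.67 and 0.91 on the 2 slides that held both groups. Of 22 Wnt targets 3 rose (DKK1, SLC12A2 and MYC; 10 higher when adjusted over the list alone), with a median of 0.30 (camera adjusted p = 4.01e-10; adjusted p = 0.000371 with an estimated correlation). Limma called 146 genes with CCT251921, 109 higher and 37 lower, against 298 with the replicate block and 743 with the slide as a block. It fell to 36 with scaling between arrays, 15 in a fit to the compared arrays alone, 96 with Cy3 alone and 72 without CCT251921 replicate 1. With 1 array left out KIAA0513 kept its call in 4 of 6 fits, KLF2 and WNT11 in 3 and SMIM5 in 1.

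With MSC2530818, 19 of the 20 genes were called, RASD1 at 2.22 ± 0.24, SLC35D3 at 1.76 ± 0.23 and KRT23 at 1.36 ± 0.21; KLF2 stood at -0.55 (adjusted p = 0.13, and 0.0168 with the replicate block). H1-10, a linker histone gene, fell by 1.07 ± 0.21 (adjusted p = 0.00495). Of 22 Wnt targets 4 rose, SLC12A2 (0.99), DKK1 (0.86), RNF43 (0.52) and the adhesion receptor CD44 (0.49), and 8 were higher and 1 lower when adjusted over the list alone. Their median was 0.28 (camera adjusted p = 3.42e-11; adjusted p = 0.000279 with an estimated correlation). In the cholesterol list INSIG1 (0.93) and SQLE (0.58) rose, with a median of 0.13 (camera adjusted p = 0.00115; adjusted p = 0.534 with an estimated correlation). The total was 129 genes, 88 higher and 41 lower, against 294 with the replicate block and 947 with the slide as a block. Scaling between arrays left 6, a fit to the compared arrays alone 2 and Cy3 alone 55. It fell to 33 without MSC2530818 replicate 1, 51 without DMSO replicate 1, 82 without MSC2530818 replicate 2 and 85 without MSC2530818 replicate 3. MSC2530818 replicate 3 was also 1 of 2 arrays that stood apart in signal over background, without which the count was 79. Leaving out 1 array at a time, EDN1, GASAL1 and H1-10 kept their calls in 5 of 6 fits, HCFC2 and TMEM107 in 2, and CDKN2D, FGFBP1 and KIAA0513 in none.

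SEL120-34A changed the most genes, 785, of which 368 were higher and 417 lower. RASD1 rose by 2.18 ± 0.24, AGRP, an antagonist of melanocortin receptors, by 1.55 ± 0.17 (adjusted p = 2.96e-08) and IHH, a hedgehog ligand, by 1.55 ± 0.38 (adjusted p = 0.00966). SRSF7, a splicing factor, fell by 1.28 ± 0.08 (adjusted p = 3.89e-15, and -0.69 by another probe), TNFRSF12A by 1.19 ± 0.11 (adjusted p = 7.8e-10) and SMIM5 by 1.35 ± 0.28 (adjusted p = 0.00173, and -0.33 by another probe). Of the 20 genes, EDN1 (0.76, adjusted p = 0.0803), WNT11 (0.42, adjusted p = 0.211) and CDKN2D (-0.36, adjusted p = 0.118, and 0.0338 with the replicate block) were not called. Of 22 Wnt targets 7 rose (10 higher when adjusted over the list alone), among them DKK1 (0.70), MYC (0.65) and CD44 (0.44), with a median of 0.34 (camera adjusted p = 7.6e-07; adjusted p = 0.00982 with an estimated correlation). Of the cholesterol genes 5 rose (7 higher when adjusted over the list alone), such as INSIG1 (1.51), SQLE (0.70) and SREBF1 (0.76), the gene of a sterol-sensing transcription factor. Their median was 0.31 (camera adjusted p = 5.39e-11; adjusted p = 0.0338 with an estimated correlation, and adjusted p = 0.0606 with an estimated correlation and the slide as a block). The count was 1264 with the replicate block and 1944 with the slide as a block, 254 with scaling between arrays, 18 in a fit to the compared arrays alone and 395 without SEL120-34A replicate 3. FGFBP1 (0.81) turned to -0.11 with the scanner software's processed signals and TMEM107 (-0.61) to 0.0093 with Cy3 alone. With 1 array left out CD24 and KLF2 kept their calls in 5 of 6 fits, IHH and KIAA0513 in 3 and FGFBP1 in 2.

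With Senexin B, RASD1 (1.51 ± 0.24, adjusted p = 0.00138), EDN1 (1.22 ± 0.26, adjusted p = 0.0211), SLC35D3 (1.09, adjusted p = 0.0199), RDH10 (0.94, adjusted p = 0.00138) and DKK1 (0.64, adjusted p = 0.0421) rose. H1-10 fell by 1.02 ± 0.21 (adjusted p = 0.0199), SERTAD1 by 0.66, TNFRSF12A by 0.62 and CDKN2C by 0.54; the other 12 of the 20 genes were not called. EDN1 turned to -0.19 with Cy3 alone, and kept its call in 3 of the 6 fits that left out 1 array (0.80 to 1.46). In those fits RDH10 and TNFRSF12A kept theirs in 5, SERTAD1 in 3, CDKN2C, H1-10 and SLC35D3 in 2 and DKK1 in 1. With the replicate block CD24 (0.55, adjusted p = 0.000304), WNT11 (0.81, adjusted p = 0.0339) and GASAL1 (-0.42, adjusted p = 0.0476) were called too. Of 22 Wnt targets, SLC12A2 (0.75) and DKK1 rose and 7 were higher when adjusted over the list alone, with a median of 0.29 (camera adjusted p = 5.98e-09; adjusted p = 0.00142 with an estimated correlation). In all 22 genes changed, 18 higher and 4 lower, against 46 with the replicate block and 504 with the slide as a block. Scaling between arrays left 0, a fit to the compared arrays alone 1 and Cy3 alone 1. The count was 8, 13 and 10 without Senexin B replicate 1, 2 and 3, 10 without DMSO replicate 1 and 79 without DMSO replicate 3. DMSO and treated arrays shared a slide for only 1 of 3 pairs with Senexin B and with SEL120-34A. Within the slides that held both groups, the mean of the Wnt targets lay between 0.28 and 0.40 with the 4 compounds other than CCT251545.

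Called with each of the 5 compounds were 12 genes, 9 higher and 3 lower: RASD1, RDH10, DKK1, SLC35D3, SLC12A2, MYCL (a MYC family transcription factor), SOX2 (a stem cell transcription factor), PCMTD2 and VIM-AS1 rose, and CDKN2C, SERTAD1 and TNFRSF12A fell. The genes in this list beyond those named above were chosen after their values were seen. With CCT251545, CCT251921 shared 32 higher and 11 lower genes (0.290 and 0.0288 for independent lists), MSC2530818 36 and 10 (0.234 and 0.032), SEL120-34A 32 and 11 (0.98 and 0.325) and Senexin B 12 and 3 (0.0479 and 0.00312). No gene was called in opposite directions. In 100 simulations of unchanged groups against the same DMSO arrays the highest number of shared calls was 0. Unchanged groups yield almost no calls, so this cannot tell how far shared arrays raise the overlap of called genes. Part of the excess may come from the shared DMSO arrays.

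**Figure D2:**
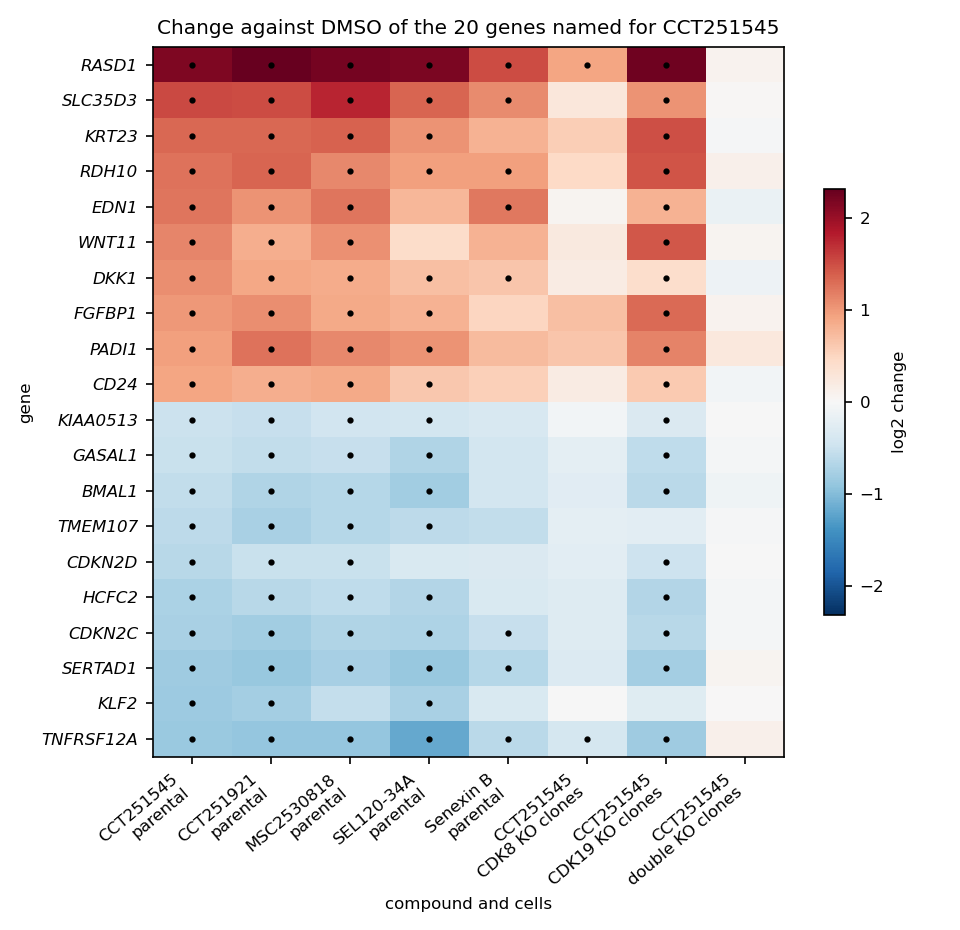
Log2 change against DMSO (colour) of the 20 genes named for CCT251545 (vertical axis) with 5 compounds in parental cells and with CCT251545 in the clones (horizontal axis); black dots mark adjusted p under 0.05, each group n = 3 arrays per cell line or clone. RASD1 stood at 2.16 with CCT251545 in parental cells, 0.92 in CDK8 KO clones, 2.26 in clones labelled CDK19 KO and 0.08 in double KO clones.

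Direct comparisons of each compound with CCT251545 in parental cells asked where their effects differed; the doses of the other compounds are not stated, so they could not be matched. INSIG1 was higher with CCT251921 than with CCT251545 (1.62 ± 0.23, adjusted p = 0.000237), 1 of 3 genes that limma called in that comparison, all higher. The count was 5 with the replicate block, 9 with the slide as a block, 0 with scaling between arrays, 0 in a fit to the compared arrays alone, 1 without CCT251545 replicate 1, 1 without CCT251921 replicate 1 and 5 without CCT251921 replicate 2. All 21 cholesterol and fatty acid synthesis genes were above 0 (13 higher when adjusted over the list alone), with a median difference of 0.41 (camera adjusted p = 3.58e-43; adjusted p = 6.27e-06 with an estimated correlation). SEL120-34A differed from CCT251545 in 252 genes, 135 higher and 117 lower. AGRP (1.44 ± 0.17, adjusted p = 3.4e-07), the guanylate cyclase activator GUCA1B (1.24 ± 0.13, adjusted p = 3.07e-08, and 0.31 by another probe) and FAM200B (1.12 ± 0.20, adjusted p = 0.000744) were higher. SRSF7 (-1.13 ± 0.08, adjusted p = 3.42e-13) and HNRNPDL (-1.02 ± 0.11, adjusted p = 3.07e-08), an RNA-binding protein gene, were lower, with -0.71 and -0.35 by other probes. That count was 419 with the replicate block and 812 with the slide as a block, 58 with scaling between arrays, 0 in a fit to the compared arrays alone, 165 with Cy3 alone, 127 without SEL120-34A replicate 3 and 162 without CCT251545 replicate 3. For MSC2530818 and for Senexin B against CCT251545 limma called 0 genes. At an unadjusted p under 0.05 were 410 and 661, each fewer than 0.05 of the 15392 genes tested. Both counts of called genes stayed at 0 with the replicate block and were 0 and 16 with the slide as a block. Cholesterol genes ranked lower with Senexin B than with CCT251545 (median -0.21, camera adjusted p = 8.64e-07; adjusted p = 0.369 with an estimated correlation).

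The clones were treated to ask whether the response to CCT251545 needs the kinases. In CDK8 KO clones RASD1 rose by 0.92 ± 0.17 (adjusted p = 0.0132), INSIG1 by 0.79 ± 0.16 (adjusted p = 0.0375), the kinase SGK1 by 0.62 ± 0.10 (adjusted p = 0.00232) and SOX2 by 0.49 ± 0.09 (adjusted p = 0.0109). TNFRSF12A fell by 0.41 ± 0.08 (adjusted p = 0.0132). When each of the 12 arrays was left out in turn, INSIG1 kept its call in 1 fit, without CDK8 KO clone 2 DMSO replicate 3 (0.73 to 0.86 over the fits), RASD1 (0.75 to 1.10) and TNFRSF12A (-0.47 to -0.35) in 6, SOX2 in 10 and SGK1 in 12. FGFBP1 (0.69, adjusted p = 0.0979) and PADI1 (0.64, adjusted p = 0.0761) were called with the replicate block (adjusted p = 0.00585 and 0.0279), and the other 16 of the 20 genes were not called. All 21 cholesterol and fatty acid synthesis genes were above 0 (10 higher when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 1.38e-29; adjusted p = 0.000179 with an estimated correlation). The 22 Wnt targets had a median of 0.08 (camera adjusted p = 0.00303; adjusted p = 0.14 with an estimated correlation, and adjusted p = 0.0176 with an estimated correlation and the replicate block), none of them called. On single slides the mean of the Wnt targets lay between 0.04 and 0.14 and that of the cholesterol genes between 0.105 and 0.36. Limma called 7 genes, 6 higher and 1 lower, against 16 with the replicate block and 45 with the slide as a block. Scaling between arrays left 0, a fit to the compared arrays alone 0 and Cy3 alone 3. The count was 2, 3 and 2 without CDK8 KO clone 1 CCT251545 replicate 3, DMSO replicate 1 and DMSO replicate 2. It was 15, 4, 1 and 1 without CDK8 KO clone 2 CCT251545 replicate 1, 2 and 3 and DMSO replicate 1.

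In the clones labelled CDK19 KO the compound changed many genes. RASD1 rose by 2.26 ± 0.17 (adjusted p = 1.7e-12), KRT23 by 1.49, RDH10 by 1.46 and WNT11 by 1.43, and 18 of the 20 genes were called in the direction seen in parental cells (not KLF2 at -0.27, adjusted p = 0.237, nor TMEM107 at -0.25, adjusted p = 0.191). SBSPON, a secreted protein gene, rose by 1.62 ± 0.21 (adjusted p = 1.21e-06), and CEACAM6, an intestinal adhesion glycoprotein well above background on 1 of 6 DMSO arrays, by 1.56 ± 0.23 (adjusted p = 1.44e-05). The vitamin D receptor gene VDR fell by 0.98 ± 0.11 (adjusted p = 1.73e-08), the chemotactic receptor gene GPR183 by 0.89 ± 0.11 (adjusted p = 6.42e-07) and SMIM5 by 1.03 ± 0.20 (adjusted p = 0.000673), though another SMIM5 probe gave -0.11. Of 22 Wnt targets 11 rose and 1 fell (12 higher and 1 lower when adjusted over the list alone), with PROX1 at 1.11 and BAMBI at 0.75 and a median of 0.34 (camera adjusted p = 4.6e-12; adjusted p = 0.000154 with an estimated correlation); on single slides the list's mean lay between 0.26 and 0.38. Of 21 cholesterol genes 7 rose, such as INSIG1 (0.84) and SQLE (0.59), with a median of 0.21 (camera adjusted p = 1.07e-10; adjusted p = 0.0426 with an estimated correlation). The mean of that list was above 0 in 5 of 6 pairs on single slides and ranged from -0.17 to 0.50, the negative pair being 1 of clone 2 that holds an array standing apart in signal over background. Of 16 intestinal markers CEACAM6, CEACAM5 (0.67) and the transcription factor CDX2 (0.71) rose (camera adjusted p = 0.00119; adjusted p = 0.158 with an estimated correlation, and adjusted p = 0.0042 with an estimated correlation and the slide as a block). Limma called 661 genes for the mean of both clones, 302 higher and 359 lower; clone 1 alone gave 114, clone 2 alone 312, and 64 were called in both. The count was 1084 with the replicate block, 2016 with the slide as a block, 278 with scaling between arrays and 345 in a fit to the compared arrays alone. The mean of both clones rests on more arrays than the parental comparison, with a median standard error of 0.097 against 0.138. The 661 genes therefore do not show a wider response than the 53 called in parental cells. With CCT251545 in parental cells these clones shared 33 higher and 10 lower genes (0.804 and 0.28 for independent lists), from different arrays.

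In double KO clones CCT251545 changed no gene past the threshold: limma called 0, with 116 at an unadjusted p under 0.05. The 116 are fewer than 0.05 of the 15392 genes tested, so they are no sign of further changes. RASD1 stood at 0.08 ± 0.17, and the 20 genes lay between -0.15 (EDN1) and 0.25 (PADI1). The count was 0 with the replicate block, 2 with the slide as a block, and 1 without double KO clone 1 CCT251545 replicate 1. In simulated data of this size 78% of the genes changed by 0.5 and 98% of those changed by 1 were called. Those simulated arrays varied independently, unlike the measured arrays of 1 slide, so the shares need not hold here. Cholesterol genes had a median of 0.07 (camera adjusted p = 0.00424; adjusted p = 0.637 with an estimated correlation), and markers of other cell types one of -0.10 (camera adjusted p = 0.00424; adjusted p = 0.459 with an estimated correlation).

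The difference of the responses was tested as an interaction. CCT251545 changed 21 genes otherwise in double KO clones than in parental cells, 3 higher and 18 lower in the double KO. At an unadjusted p under 0.05 were 538, fewer than 0.05 of the 15392 genes tested. RASD1 differed by -2.09 ± 0.30 (adjusted p = 0.000113), DKK1 by -1.20 ± 0.18 (adjusted p = 0.000145), RDH10 by -1.14 ± 0.19 (adjusted p = 0.00104), SLC35D3 by -1.495 ± 0.28 (adjusted p = 0.00481) and KRT23 by -1.36 ± 0.26 (adjusted p = 0.00584). The count was 50 with the replicate block and 143 with the slide as a block, but 1 with scaling between arrays and 10 with Cy3 alone. With 1 of the 18 arrays left out, KRT23 kept its call in 16 fits and SLC35D3 in 17. Wnt targets responded less in double KO clones (median -0.31, 2 genes lower; 1 higher and 7 lower when adjusted over the list alone; camera adjusted p = 5.72e-16; adjusted p = 1.32e-05 with an estimated correlation). They also responded less in CDK8 KO clones (median -0.25, no gene called; 3 lower when adjusted over the list alone; camera adjusted p = 2.76e-14; adjusted p = 3.65e-05 with an estimated correlation). Intestinal differentiation markers ranked lower in the double KO response (median -0.13, no gene called; camera adjusted p = 2.7e-05; adjusted p = 0.0945 with an estimated correlation, and adjusted p = 0.000677 with an estimated correlation and the slide as a block). For single genes limma called 0 interactions in CDK8 KO clones and 0 in clones labelled CDK19 KO. At an unadjusted p under 0.05 were 268 and 270, each again fewer than 0.05 of the genes tested. The counts of called interactions were 4 and 0 with the replicate block and 23 and 4 with the slide as a block. The CDK8 KO count was 1 without parental DMSO replicate 1. In simulated data, with arrays that varied independently, the interaction fit called 26% of the genes changed by 0.5 and 93% of those changed by 1.

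**Figure D3:**
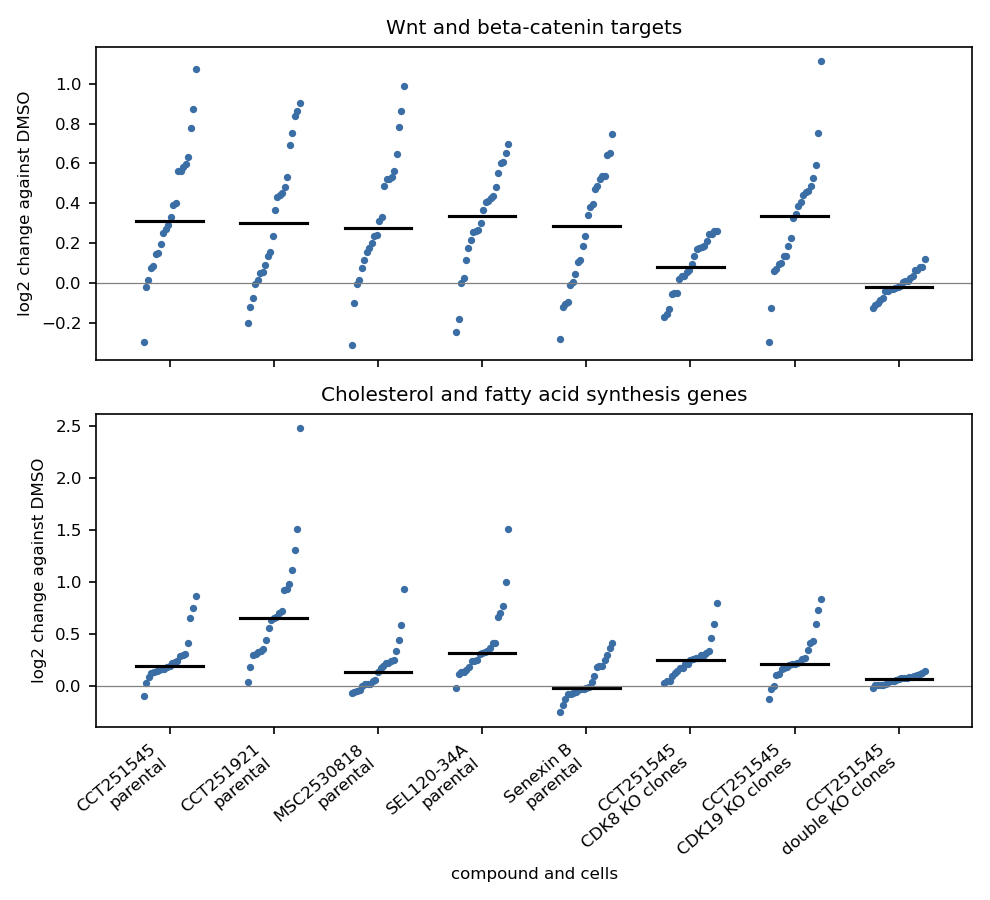
Log2 change against DMSO (vertical axis) of the 22 measured Wnt targets (top) and 21 cholesterol and fatty acid synthesis genes (bottom) by compound and cells (horizontal axis); points are genes and lines medians. The cholesterol median was 0.65 with CCT251921 and 0.19 with CCT251545, and the Wnt median was 0.31 with CCT251545 in parental cells and 0.08 in CDK8 KO clones.

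To set the compounds and clones on 1 scale, a signature was taken from the clones labelled CDK19 KO: 40 genes (28 higher, 12 lower) that CCT251545 changed at least 1.5-fold, called in both clones. Before treatment the signature already stood below parental DMSO in these clones, at -0.38 (95% interval -0.48 to -0.27) and -0.36 (-0.47 to -0.25). Its mean change, signed so that a like response is positive, was 0.72 (95% interval 0.61 to 0.83) with CCT251545 in parental cells, 0.72 (0.62 to 0.83) with CCT251921, 0.71 (0.60 to 0.82) with MSC2530818, 0.67 (0.56 to 0.77) with SEL120-34A and 0.50 (0.39 to 0.61) with Senexin B. Each had an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. The differences from CCT251545 were 0.00 (-0.10 to 0.11) for CCT251921, -0.01 (-0.12 to 0.10) for MSC2530818, -0.05 (-0.16 to 0.05) for SEL120-34A and -0.22 (-0.33 to -0.11) for Senexin B, whose exact permutation p was 0.1. With CCT251545 the signature moved by 0.34 (0.27 to 0.42) in CDK8 KO clones, positive in 6 of 6 pairs (exact permutation p = 0.005, the smallest possible), and by -0.00 (-0.08 to 0.08) in double KO clones (exact permutation p = 0.965). Against parental cells the response was lower by -0.38 (-0.51 to -0.24) in CDK8 KO and by -0.72 (-0.85 to -0.59) in double KO clones, each with an exact permutation p of 0.0119. Double KO minus CDK8 KO was -0.34 (-0.45 to -0.24, exact permutation p = 0.00216). The p-values of these differences between genotypes permute pairs pooled over both clones, so they do not measure the spread between clones. All pairs of treated and DMSO arrays in parental cells with CCT251545 and in the clones lay within slides. A second signature of 39 genes (32 higher, 7 lower), taken from parental cells with CCT251545 and sharing 18 genes with the first, moved by 0.28 (0.23 to 0.34) in CDK8 KO, 0.70 (0.64 to 0.75) in clones labelled CDK19 KO and -0.01 (-0.07 to 0.04) in double KO clones; the exact permutation p were 0.005, 0.005 and 0.545.

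**Figure D4:**
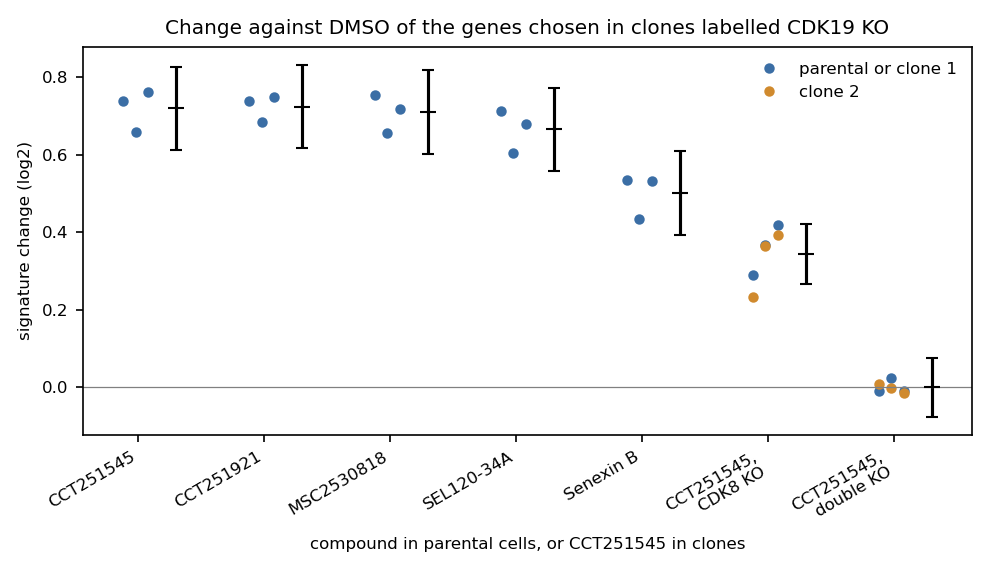
Mean signed log2 change against DMSO of the 40 signature genes (vertical axis) with 5 compounds in parental cells and with CCT251545 in CDK8 KO and double KO clones (horizontal axis); points are differences of same-numbered arrays, blue for parental cells or clone 1 and orange for clone 2, and bars the mean with its 95% interval. The mean was 0.72 with CCT251545 in parental cells, 0.34 in CDK8 KO clones and -0.00 in double KO clones.

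Untreated clones were compared with untreated parental cells. No clone with both kinases intact was measured, so loss of the kinases cannot be told apart from other differences between clones and the parental culture. In double KO clones SLITRK6, a neuronal membrane protein gene, was higher by 4.72 ± 0.14 (adjusted p = 2.89e-27) and the transcription regulator LMO2 by 3.68 ± 0.30 (adjusted p = 5.19e-13). SBSPON (3.50), the heparan sulphate enzyme HS3ST4 (3.40), the cholesterol esterifying enzyme SOAT2 (3.26), the Wnt inhibitor APCDD1 (3.03), B3GAT1 (2.84), the proton pump subunit ATP6V0A4 (2.40), P3H3 (2.32) and RAMP1 (2.30) were higher too. SLITRK6 and HS3ST4 were well above background on 1 of 3 parental arrays each, and another probe gave 0.94 for SLITRK6 and 0.35 for HS3ST4. Other probes gave 1.89 for RAMP1, -1.36 for ALDH1A1 and -1.07 for FGF9. ANXA1, a phospholipid-binding regulator of inflammation, was lower by -3.65 ± 0.26 (adjusted p = 1.51e-14), as were the retinal dehydrogenase ALDH1A1 (-3.19), the acyltransferase GPAT3 (-3.08), the keratin KRT6A (-2.89), the ubiquitin-like UBD (-2.80), the tubulin TUBB6 (-2.61), the RNA component RMRP (-2.31), FGF9 (-2.30), WWC3 (-2.26) and ISM1 (-2.14). Called in both double KO clones in 1 direction were 2163 genes, 1114 higher and 1049 lower, or 14.1% of those tested. With the slide as a block the count was 3401.

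CDK8 KO clones held less ANXA1 (-3.76 ± 0.26, adjusted p = 1.28e-14), ALDH1A1 (-3.27), UBD (-3.08) and TUBB6 (-2.56), and KRT6A, not well above background on their arrays, was lower (adjusted p = 1.85e-18), by at least 10.1-fold in Cy3 signal. Another ALDH1A1 probe gave -1.31. They held more SLITRK6 (2.49 ± 0.14, adjusted p = 2.04e-17; 0.30 by another probe), SOAT2 (2.39), the retinal reductase DHRS3 (2.35), the stress-induced mTOR inhibitor DDIT4 (2.12) and KRT23 (1.84). The clones labelled CDK19 KO held less ANXA1 (-3.32 ± 0.26, adjusted p = 7.93e-13), UBD (-3.26), ALDH1A1 (-3.19; -1.30 by another probe), KRT6A (-3.12) and the chaperone HSPA1B (-2.94). They held more DDIT4 (3.04 ± 0.40, adjusted p = 1.86e-07), the stress ligand ULBP1 (2.58; 0.67 by another probe), the EGF receptor inhibitor ERRFI1 (2.51), the netrin receptor UNC5B (2.49) and the asparagine synthetase ASNS (2.44), though another ASNS probe gave 0.01. Both CDK8 KO clones changed 1760 genes (740 higher, 1020 lower) and both clones labelled CDK19 KO 2152 (969 higher, 1183 lower), against 2917 and 3547 with the slide as a block, 1059 and 1277 with scaling between arrays, and 556 and 791 in fits to the compared arrays alone. The second fell to 1371 without CDK19 KO clone 2 DMSO replicate 3. CDK8 KO clones shared no slide with parental DMSO arrays, so no value within slides was to be had for them.

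All 6 clones changed 656 genes in the same direction, 278 higher and 378 lower. Of the NF-kappaB targets, a group of inflammatory genes, 7 of 18 were lower in CDK8 KO, 6 in clones labelled CDK19 KO and 7 in double KO clones, and none was higher. The chemokine CXCL1 stood at -2.02, -2.60 and -1.97 and the lymphotoxin gene LTB at -1.17, -0.91 and -0.94. The medians were -0.40, -0.36 and -0.38 (camera adjusted p = 5e-06, 3.47e-06 and 3.05e-05; adjusted p = 0.0467, 0.0519 and 0.0843 with an estimated correlation). When adjusted over the list alone 11, 13 and 11 were lower, and the CDK8 KO list had adjusted p = 0.084 with an estimated correlation and the slide as a block. On the shared slides the list's mean lay between -0.66 and -0.38 for double KO clones in 4 comparisons and at -0.34 for the clones labelled CDK19 KO in 1.

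The change in double KO clones was also set against the change by the compound. Across genes it correlated with that of CCT251545 in parental cells at r = 0.08 (covariance 0.00479). Simulated unchanged groups sharing the DMSO arrays gave r = 0.577 and a covariance of 0.0134; keeping the measured correlation of 0.761 between treated and DMSO arrays they gave 0.284 and 0.00322. With CCT251545 in the clones labelled CDK19 KO, which shares no array, r was 0.07, against -0.04 to 0.03 in simulated unchanged groups, whose genes vary independently. There 59 genes were higher and 61 lower in both (21.9 and 24.5 for independent lists), and 55 were called in opposite directions. With parental CCT251545, 4 genes were higher and 3 lower in both (2.97 and 0.818 for independent lists), and 8 opposite. Genes are not independent replicates, so these correlations carry no p-value.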

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

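The tests of explanations, the other splits of the arrays, the differences between signature scores, the cholesterol difference and the look at probes with no gene name were chosen only after the results were seen; the interactions of single genes and lists were planned. Clones are called by their labels, which the CDK19 probe goes against. No group held 4 arrays, so no array was tested as lying far from its group.

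CCT251545 changed 21 genes otherwise in double KO clones than in parental cells. The responses differed by -2.09 for RASD1, -1.495 for SLC35D3, -1.36 for KRT23, -1.20 for DKK1 and -1.14 for RDH10. The signature of 40 genes responded less by -0.38 in CDK8 KO and -0.72 in double KO clones than in parental cells, and by -0.34 in double KO than in CDK8 KO clones. Wnt targets responded less, with medians of -0.25 in CDK8 KO and -0.31 in double KO clones, and the mean of the cholesterol and fatty acid synthesis genes differed by -0.20 between double KO and CDK8 KO clones. Outside the named genes, 35 of 6022 tested probes with no gene name changed with CCT251545 in the clones labelled CDK19 KO (29 higher, 6 lower) and 92 with SEL120-34A in parental cells (74 higher, 18 lower), against 0 with CCT251545 in double KO clones and 0 with CCT251545 in parental cells, so these counts do not bear on a need for the kinases.

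The first pattern is the smaller CCT251545 response in CDK8 KO and double KO clones. A larger spread between replicates is argued against, since it was 0.78 times that of parental cells in these clones. That ratio does not measure the spread of the differences within pairs. Treated and DMSO arrays of 1 number correlated at 0.64 to 0.87 in parental cells. In CDK8 KO clones they correlated at 0.18 to 0.78 and in double KO clones at 0.21 to 0.64. The signature mean may already have been shifted in the untreated clones. A shift of 50% of the parental response, which would be 0.36, is argued against for 3 clones, whose intervals end below it. These are CDK8 KO clones 1 and 2 (0.13 and -0.14 from parental DMSO) and double KO clone 1 (-0.18). A smaller shift is not excluded, and the 95% interval of CDK8 KO clone 1 (0.03 to 0.24) lies above 0. A shift of 0.36 stays open for double KO clone 2 (0.38, 95% interval 0.28 to 0.49). Opposite shifts of single genes cancel in the mean. In CDK8 KO clones 1 and 2 and double KO clone 1, 25, 20 and 17 of 40 genes lay in the signature's direction. Single genes shifted before treatment are therefore not excluded. Slides are argued against, because the lowest parental difference within a slide exceeded the highest of these clones by 0.24. A need for the kinases may account for the pattern, as may another property of these clones that was not tested.

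The second pattern is the set of genes changed alike in all 6 clones. Against the 15 other parental arrays, all of cells given a compound, the median change of these genes was 0.871 times as large. Deviations of those arrays correlated with those of the same-numbered DMSO arrays (0.17 to 0.87). A chance shift of the DMSO arrays could thus be carried over, so this comparison cannot exclude chance values of the parental DMSO arrays. Slides are argued against as the whole cause, since within shared slides it was 0.934 times as large, on 2 slides with clones labelled CDK19 KO or double KO alone. A difference between clones and the parental culture not set by the kinases cannot be told apart from an effect of either kinase: 1093 genes changed alike in CDK8 KO and CDK19 KO clones (46.6 higher and 78.4 lower for independent lists, 3 opposite), which share no targeted gene, and no clone with both kinases intact was measured. With the 15 other parental arrays as controls for the clones labelled CDK19 KO, 1126 genes were alike and 16 opposite (224 alike for independent lists). In 100 simulations of unchanged clones against the same DMSO arrays at most 0 genes were called alike in all 6. Unchanged clones yield almost no calls, so that simulation cannot tell how far the shared arrays raise the overlap.

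The third pattern is the rise of cholesterol and fatty acid synthesis genes with CCT251545 in CDK8 KO clones, by a mean of 0.25 (95% interval 0.13 to 0.38) against 0.26 (0.09 to 0.43) in parental cells. Slides are argued against, as every CDK8 KO pair within a slide lay at 0.105 or higher. The mean was 0.0573 (-0.06 to 0.18) in double KO clones, lower than in CDK8 KO clones (exact permutation p = 0.00433). That p pools the pairs of both clones and does not measure the spread between clones. Before treatment, however, these genes already stood 0.38 (0.23 to 0.53) above parental DMSO in double KO clones (0.17 in clone 1 and 0.58 in clone 2) and 0.20 (0.06 to 0.35) in CDK8 KO clones, which may leave less room for a rise. An action of the compound that needs neither kinase therefore cannot be told apart from an action through CDK19.

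Of the 10 splits of the 6 arrays of each comparison in parental cells, too few for a share under 0.05, CCT251545 gave 53 genes in the real split and up to 1869 in the others, 5 of 10 being as large. The 4 others as large kept both arrays of replicate 1, which lay on 1 slide, on the same side, so the large counts point to slide or replicate structure; among the 4 splits that part every numbered pair the highest other was 0. The real split and the highest other gave 146 and 0 genes for CCT251921, 129 and 1 for MSC2530818, 788 and 304 for SEL120-34A, 22 and 1 for Senexin B, and against CCT251545 3 and 0 for CCT251921 and 252 and 4 for SEL120-34A, with 1 of 10 as large in each. For MSC2530818 and Senexin B against CCT251545 all 10 splits gave 0 genes. Among the splits that part every pair, SEL120-34A had a highest other of 0 and its difference from CCT251545 one of 4.

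For the clones 100 splits were drawn, and missing values were filled in, which moved some counts by a few genes. For the untreated clones 1 of 100 splits, the real one, was as large each. The real split and the highest other gave 1763 and 579 genes for CDK8 KO. They gave 2155 and 1115 for CDK19 KO and 2166 and 1271 for double KO. An arbitrary division of the arrays is thus argued against. A shift of the parental DMSO arrays, which all these counts share, is not excluded. Nor is a shift between slides for CDK8 KO clones, which shared no slide with those arrays. For CCT251545 in the clones labelled CDK19 KO an arbitrary division is argued against too, with 662 genes and 3 of 100 splits as large. The highest other, 1144, is again more than the real count, and was 102 among the 32 splits that part every pair. Over all 100 splits, which need not part the numbered pairs, chance cannot be excluded for CCT251545 in CDK8 KO clones (7 genes, 8 splits as large, highest other 1465) nor for the count of interactions in double KO clones (21 genes, 28 splits as large, highest other 952). Among the splits that, like the real one, part every pair, 1 of 32 and 2 of 60 were as large, the real ones included, with highest others of 0 and 21, and both shares lie under 0.05. For CCT251545 in double KO clones and for the interactions in CDK8 KO and in CDK19 KO clones the real count was 0, so all 100 splits were as large, with highest others of 0, 1221 and 1490, and of 0, 145 and 728 among the splits that part every pair. Some splits of an interaction exchange treated and DMSO arrays in parental cells alone, which adds the parental response to that of the clones. Counts of 145 or more can arise that way, so they do not show structure among the arrays. Evidence for such structure beyond the groups rests on the fits with slide and replicate blocks.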

How the results depend on the processing

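Scaling between arrays, the fixed slide block and the fit without the 2 arrays that stand apart in signal were chosen after seeing the data; the other alternatives were planned. Clones are called by their labels. Between-array Aquantile normalisation was not run, because it leaves the log ratios of single-array loess unchanged by construction. With the deposited matrix, means over all probes of a gene, or no filter on dim probes, every count stayed within 1.5 times its value. The deposited matrix holds nearly the same values with the sign turned (r = -1), so its like counts are no separate check. The other CDK8 probe kept the direction of each CDK8 KO and double KO clone. Its mean log2 ratio was 0.69 in parental DMSO, 0.17 and 0.42 in CDK8 KO and 0.33 and 0.19 in double KO clones 1 and 2. It was also lower in the clones labelled CDK19 KO (0.37 and 0.29), so it does not bear out the labels. Where values changed, the cause was not tested, unless the setting itself shows it. Genes dim in Cy3 limit what can be seen: the lowest share of probes well above background on an array was 39.6%, and a fall below background is seen only as a bound.

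With the replicate block, paired as the check of numbers allows, CCT251545 gave 149 genes in parental cells, 16 in CDK8 KO and 1084 in CDK19 KO clones, CCT251921 298, MSC2530818 294, SEL120-34A 1264 and Senexin B 46. Against CCT251545, CCT251921 gave 5 and SEL120-34A 419, and interactions were 4 in CDK8 KO and 50 in double KO clones. It kept every gene called without it. Of 70 calls of gene lists it kept 68 and it made 75. Notch targets with CCT251921 (camera adjusted p = 0.0635) and MYC and ribosome biogenesis genes with CCT251545 in CDK19 KO clones (0.0563) lost their calls. Gained, without an estimated correlation, were 7 calls: immediate-early genes with CCT251545 and CCT251921 and in the interactions in CDK8 KO and double KO clones, heat shock genes with SEL120-34A and in the interactions in CDK8 KO clones, and cholesterol genes with MSC2530818 against CCT251545. Knockout and parental arrays share only a number, and the block gave 2354, 2889 and 2812 genes in untreated CDK8 KO, CDK19 KO and double KO clones. With the slide as a fixed block the compounds gave 312, 743, 947, 1944 and 504 genes in the order CCT251545, CCT251921, MSC2530818, SEL120-34A and Senexin B. Against CCT251545 it gave 9 for CCT251921, 812 for SEL120-34A and 16 for Senexin B. CCT251545 gave 45 in CDK8 KO, 2016 in CDK19 KO and 2 in double KO clones, interactions were 23, 4 and 143, and the untreated clones gave 2917, 3547 and 3401. With the slide as a random block the same results were 296, 666, 798, 1894 and 319 for the compounds, 12 and 747 for CCT251921 and SEL120-34A against CCT251545, 39, 1957 and 2 for CCT251545 in the clones, 23, 3 and 135 for interactions, and 2879, 3542 and 3382 for untreated clones.

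With scaling between arrays the compounds gave 6, 36, 6, 254 and 0 genes. CCT251921 and SEL120-34A differed from CCT251545 in 0 and 58, CCT251545 gave 0 in CDK8 KO and 278 in CDK19 KO clones, 1 gene had an interaction in double KO clones, and 1059 and 1277 changed in untreated CDK8 KO and CDK19 KO clones. In a fit to the compared arrays alone, which leaves fewer arrays to estimate the spread, the compounds gave 1, 15, 2, 18 and 1 genes and 0 and 0 differed for CCT251921 and SEL120-34A against CCT251545. There CCT251545 gave 0 in CDK8 KO and 345 in CDK19 KO clones, and 556 and 791 genes changed in untreated CDK8 KO and CDK19 KO clones. Without the arrays that stand apart MSC2530818 gave 79.

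With Cy3 alone the counts were 96 for CCT251921, 55 for MSC2530818, 1 for Senexin B, 165 for SEL120-34A against CCT251545, 3 for CCT251545 in CDK8 KO clones, and 3, 1 and 10 for interactions in CDK8 KO, CDK19 KO and double KO clones. The CDK19 KO signature moved by 0.79 with CCT251545, 0.79 with CCT251921, 0.78 with MSC2530818 and 0.76 with SEL120-34A, and the parental signature by 0.40 in CDK8 KO, 0.97 in CDK19 KO and 0.0265 in double KO clones. The CDK19 level lost its call in CDK19 KO clone 1 (0.62, adjusted p = 0.0733) and double KO clone 1 (0.34, adjusted p = 0.329). The likeness of the double KO change to CCT251545 was 0.119 in parental and 0.101 in CDK19 KO cells. EDN1 with Senexin B turned to -0.19 and TMEM107 with SEL120-34A to 0.0093 with Cy3 alone, and FGFBP1 with SEL120-34A to -0.11 with the scanner software's processed signals. With those signals interactions were 1 in CDK8 KO and 1 in CDK19 KO clones. Without background subtraction the CDK8 KO interactions were 1 and the likeness in parental cells 0.132; over genes called in either it was 0.0967, and 0.0924 in CDK19 KO cells. With an estimated correlation 15 of 70 calls of gene lists held.

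A log2 change of at least 1, stricter by construction, left 8, 14, 11, 24 and 4 genes for the compounds, 1 and 5 for CCT251921 and SEL120-34A against CCT251545, 0 and 20 for CCT251545 in CDK8 KO and CDK19 KO clones, 6 interactions in double KO clones, and 122, 176 and 203 genes in untreated CDK8 KO, CDK19 KO and double KO clones. Called in both clones separately were 0 and 64 genes for CCT251545 in CDK8 KO and CDK19 KO clones and 9 interactions in double KO clones. The mean of both clones as 1 contrast gave 3842, 4091 and 4640 genes in untreated clones. Signatures limited to genes changed by at least 1 moved by 1.13, 1.14, 1.11, 0.97 and 0.79 with the compounds, and by 0.42 and 1.28 in CDK8 KO and CDK19 KO clones.

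Leaving out 1 array at a time, in a fit that assumes the remaining arrays vary like the other groups, gave 31 to 79 genes for CCT251545, 72 to 155 for CCT251921, 33 to 179 for MSC2530818, 395 to 707 for SEL120-34A and 8 to 79 for Senexin B. It gave 1 to 5 for CCT251921 and 127 to 208 for SEL120-34A against CCT251545, 1 to 15 for CCT251545 in CDK8 KO and 0 to 1 in double KO clones, 0 to 1 for interactions in CDK8 KO, and 1371 to 2219 for untreated CDK19 KO clones. The parental signature in double KO clones lay between -0.0312 and 0.0108, the CDK19 level in double KO clone 1 between 0.44 and 0.79, and the CDK8 level in double KO clone 2 between -0.90 and -0.67.

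The split of higher and lower calls moved by over 10 points in untreated clones with Cy3 alone, to 473 and 1057 in CDK19 KO (969 and 1183 in the report) and 419 and 1011 in CDK8 KO clones (740 and 1020). It moved for MSC2530818 to 102 and 24 without background subtraction (88 and 41). With scaling between arrays it was 38 and 20 for SEL120-34A against CCT251545 (135 and 117), 5 and 1 for MSC2530818, 4 and 2 for CCT251545 (41 and 12), and 0 and 1 for the interactions in double KO clones (3 and 18). With Cy3 alone it was 2 and 1 for CCT251545 in CDK8 KO clones (6 and 1), 1 and 0 for Senexin B (18 and 4), and 2 and 1 for CCT251921 against CCT251545 (3 and 0). The median of all genes stood at -0.11 for CDK19 KO clone 2 and -0.11 for double KO clone 1 with the processed signals, and to -0.11 for CDK8 KO clone 1 and -0.10 for double KO clone 1 with Cy3 alone, so changes of that size in the clones are not told apart from a general shift.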

Other observations

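The splicing factor list, the comparisons of knockout clones with each other and the simulations were chosen only after the results were seen; the other lists were planned.

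Genes of the ATF4 and unfolded protein response list differed between the clones labelled CDK19 KO and parental cells. Of 16 ATF4 and unfolded protein response genes 11 were higher and 1 lower, with a median of 1.45 (camera adjusted p = 2.73e-08; adjusted p = 0.154 with an estimated correlation). The serine synthesis enzyme PHGDH (1.82), DDIT4 (3.04) and the transcription factor XBP1 (1.07) were higher, and the chaperone of the endoplasmic reticulum HSPA5 was lower (-1.52). In CDK8 KO clones 4 of these genes were higher and 1 lower (camera adjusted p = 0.0101; adjusted p = 0.591 with an estimated correlation). Heat shock genes were lower in CDK8 KO, CDK19 KO and double KO clones (4, 6 and 3 of 10; camera adjusted p = 0.00402, 3.87e-05 and 0.0278; adjusted p = 0.556, 0.194 and 0.941 with an estimated correlation, and adjusted p = 0.034 in CDK19 KO with an estimated correlation and the slide as a block). The co-chaperone DNAJB1 stood at -1.20, -1.39 and -1.18. Of 23 interferon targets 7 were lower in CDK8 KO (camera adjusted p = 0.000218; adjusted p = 0.224 with an estimated correlation) and 10 in CDK19 KO clones (camera adjusted p = 7.64e-05; adjusted p = 0.154 with an estimated correlation), IFIT1 at -1.33 and -1.37. Of 13 targets of AhR and NRF2, 4, 4 and 5 were lower (camera adjusted p = 0.0142, 0.0169 and 0.0122; adjusted p = 0.134, 0.114 and 0.0863 with an estimated correlation, and adjusted p = 0.0469 in double KO with an estimated correlation and the slide as a block), with the aldehyde dehydrogenase ALDH3A1 at -1.56, -1.58 and -1.49 and the haem oxygenase HMOX1 at -1.19, -1.06 and -1.05.

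Of 21 hypoxia and glycolysis genes 7 were higher in clones labelled CDK19 KO, such as PDK1 (1.12) and CA9 (1.05), with camera adjusted p = 1.85e-05 (adjusted p = 0.114 with an estimated correlation). Cholesterol genes were higher in double KO clones (6 of 21, SCD at 1.07 and INSIG1 at 1.47; camera adjusted p = 0.000311; adjusted p = 0.446 with an estimated correlation). Intestinal markers ranked higher with CCT251545 in CDK8 KO clones (camera adjusted p = 0.0232; adjusted p = 0.406 with an estimated correlation, and adjusted p = 0.0236 with an estimated correlation and the slide as a block). In untreated cells they were lower in clones labelled CDK19 KO (4 of 16, CEACAM6 at -2.39 though well above background on 1 of 6 DMSO arrays of these clones; camera adjusted p = 0.0332; adjusted p = 0.304 with an estimated correlation). MYC and ribosome biogenesis genes were lower in CDK8 KO (4 of 16; camera adjusted p = 0.0201; adjusted p = 0.591 with an estimated correlation) and double KO clones (3 lower and 1 higher; camera adjusted p = 0.0206; adjusted p = 0.941 with an estimated correlation). With CCT251545 in the clones labelled CDK19 KO, TGF-beta targets (TGIF1 at 0.52 and SMAD6 at 0.48; camera adjusted p = 0.0359; adjusted p = 0.216 with an estimated correlation) and Notch targets (camera adjusted p = 0.0359; adjusted p = 0.104 with an estimated correlation) ranked higher. Notch targets also ranked higher with CCT251921 in parental cells (JAG1 at 0.62; camera adjusted p = 0.0453; adjusted p = 0.0993 with an estimated correlation, and 0.0635 with the replicate block). Cell cycle genes (camera adjusted p = 0.00331; adjusted p = 0.473 with an estimated correlation) and immediate-early genes (camera adjusted p = 0.039; adjusted p = 0.471 with an estimated correlation) ranked lower with CCT251545 in the clones labelled CDK19 KO. The Mediator kinase module, p53 targets and epithelial and mesenchymal markers passed the threshold in none of the 18 comparisons, and other cell types only with CCT251545 in double KO clones. Of the fibroblast genes COL1A2, DCN, COL1A1 and LUM had median ratios to the reference of -4.63, -4.42, -2.75 and -2.63; COL3A1 (-0.11) and PDGFRB (-2.27) were well above background on 0 and 1 of 54 arrays and show little.

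SRSF7 and HNRNPDL were lower with SEL120-34A, and a hypothesis is that splicing factor genes fell as a group. Of 24 other SR protein and hnRNP genes 5 fell and none rose, with 19 below 0 and a median of -0.13 (camera p with an estimated correlation 0.00411), and 3 fell against CCT251545 (0.00484). SRSF3 stood at -0.87 and SRSF6 at -0.71. With CCT251545 the same list gave 0.347 and no calls. The list was written after SRSF7 had been seen, so the result may rest on that choice.

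Knockout and inhibitor changes were little alike: against CCT251545 in the clones labelled CDK19 KO the double KO change gave 0.07 and the CDK8 KO change 0.0412, above the highest simulated values of 0.0270 and 0.0409. A second hypothesis was that clones labelled CDK8 KO differ from clones labelled CDK19 KO as inhibitor-treated parental cells differ from DMSO. Across genes the correlation was 0.197, with no shared array, against -0.03 to 0.03 in simulated unchanged groups, whose genes vary independently, so that the range is narrow. Of the called genes 11 were higher and 4 lower in both (2.02 and 0.467 for independent lists), and 3 were opposite. Double KO minus CDK19 KO clones gave 0.167, with 19 higher, 6 lower (6.63 and 1.41 for independent lists) and 7 opposite. Double KO minus CDK8 KO clones gave 0.0705 (simulated -0.03 to 0.03), with 12 higher, 1 lower (3.62 and 0.628 for independent lists) and 9 opposite. The higher values both subtract the clones labelled CDK19 KO, so part of them could come from these clones rather than from loss of CDK8. The 0.0705 does not rest on those clones, but both genotypes behind it are labelled as lacking CDK8. It therefore does not bear on loss of CDK8. Set directly against parental CCT251545, with DMSO arrays shared, the CDK19 KO change gave -0.0762 (1 higher and 3 lower in both, 15 opposite). The CDK8 KO change gave 0.0408 (8 higher and 4 lower in both, 11 opposite). A correlation of 0.197 also leaves most of the difference between the clones outside the hypothesis.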
